A study of Mus musculus with 12 samples.

How the data were processed

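The data are counts of sequencing reads per gene from 12 libraries of mouse CD8 T cells, which were cultured in 4 conditions and harvested at day 7. Per the labels, the cells came from C57BL/6 spleen, RNA was isolated with a column kit, and stranded mRNA libraries were made with an Illumina TruSeq kit. Reads were aligned with STAR and assigned to genes with featureCounts on the mouse genome GRCm38, per the submitters' processing notes. Versions of these tools, the annotation release, the strand setting of the counting and the treatment of reads with several matches were not given in the sources used here. The deposited values are raw counts per gene for each sample, which the authors had not normalized: they are whole numbers that sum to 18300206 to 33477037 per library. The tables list 46078 genes by Ensembl identifier, 0 entries name no gene and 0 columns of samples were left unused. Symbols, coordinates and exons were taken from GENCODE for GRCm38, in which 45229 of the identifiers (98.2%) were found.

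Samples were grouped by the treatment in their labels into IL-2 + IL-15, RA, TGFβ and TGFβ + RA, with 3 samples each, and 0 samples were left out. Totals were 26987909, 25121584 and 33477037 counts for IL-2 + IL-15 replicates 1 to 3, 22946716, 27560208 and 21359384 for RA, 25633171, 23710238 and 24324455 for TGFβ, and 18300206, 31120721 and 26494995 for TGFβ + RA. Replicates of one group differed by more than counting noise, with a chi-square per degree of freedom over genes of 3.79 to 24.0, so each library was counted as 1 replicate. RA replicate 3 differed most from the others of its group (24.0 and 20.4), followed by IL-2 + IL-15 replicate 1 (9.27 and 12.5).

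The design, the tests of the contrasts and of the lists, the gene lists and the rule for named genes were chosen before the data were examined. Tests and alternatives chosen later are named as such where they are given. Genes were filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3 (minimum count 10, by group), which kept 14009 genes holding at least 99.9% of the counts of each library. Libraries were scaled by TMM, and all 12 entered 1 quasi-likelihood model with a mean per group and no covariate (8 residual degrees of freedom). In all, 5 contrasts of 2 groups and the interaction were tested with glmQLFTest, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are those of edgeR (prior count 0.125), and each SE was taken as the size of the fold change over the square root of F. Such an SE can understate the error where a group has few counts, so it is no measure of precision for the largest fold changes. CPM values are TMM-scaled, and log2 CPM with a prior count of 2 were computed from the deposited counts for principal components and list tests. A count of 0 allows up to 3 counts, and a group with 2 or 3 counts in all is given as a ratio with an exact 95% interval that covers counting error only.

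Gene lists were tested with camera of limma 3.58.1 on log2 CPM, with a preset correlation between genes of 0.01, two-sided, and Benjamini-Hochberg adjustment over the lists of a contrast with at least 3 tested members. Camera with an estimated correlation and the rotation test fry were alternatives. The 25 lists, fixed from general knowledge of the field and not from these samples, were residency genes, circulation and egress genes, gut homing, skin homing, retinoid receptors and response, TGFβ pathway and feedback targets, cytotoxic molecules, cytokines and chemokines, cytokine receptors, inhibitory receptors, effector and memory transcription factors, NK receptors, integrins and adhesion, cell cycle, glycolysis, cholesterol and lipid metabolism, interferon-stimulated genes, immediate-early and stress genes, CD8 T cell identity, and markers of CD4 T cells, gamma delta T cells, NK cells, B cells, myeloid and dendritic cells, and erythroid and stromal cells. Some genes are in more than 1 list.

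Genes are named by a fixed rule. It takes a panel of 20 genes of residency, homing, egress and cytotoxicity. It adds the 5 highest and 5 lowest log2 fold changes of each contrast among called genes with a mean of at least 5 CPM and, between 2 groups, no overlap of the 3 values of one group with the 3 of the other, a split that chance gives for 1 of 10 groupings in each direction or the other; predicted gene models were left out. It also adds up to 4 members of each list with the smallest adjusted p among those called. Some genes that the rule takes are not reported here. Correlations of effects are across genes, with a jackknife SE over libraries. Single measures of libraries were compared by an exact two-sided permutation test, which with 3 against 3 samples gives 10 splits and no p below 0.1.

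The alternatives were DESeq2 size factors in place of TMM, no filter on low counts, the Wald test of DESeq2 1.42.0, the replicate number as a block, glmTreat against a minimum change of 1.5-fold, leaving out each replicate in turn, only the 6 samples of a comparison in the fit, and a prior count of 5 for the correlations. Ranges of adjusted p given for single genes leave out glmTreat, which tests a larger change. A further alternative was added after the data were seen: the 9 libraries left without IL-2 + IL-15 replicate 1 and RA replicate 3, which lie apart on later principal components, and TGFβ + RA replicate 3, which holds transcripts of myeloid cells such as neutrophils. Other groupings of the libraries were also counted. The replicate numbers did not meet the fixed rule for pairing.

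The model was tested on simulated data drawn from the means, spread and library sizes of these samples, with 67, 67 and 66 genes changed 1.5-, 2- and 4-fold. For RA against IL-2 + IL-15 it recovered 74.6% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 4-fold, with 7 false calls among the unchanged of 13754 genes. For TGFβ against IL-2 + IL-15 the shares were 77.6%, 94.0% and 100%, with 16 false calls, and for the interaction 53.7%, 91.0% and 100%, with 9 false calls. A simulation without any interaction gave 0 interaction calls with edgeR among 13758 genes, and 591 at an unadjusted p under 0.05. In a simulation for camera, the 1 changed list was called and 0 of 23 unchanged lists were. Genes were drawn independently of each other there, so it cannot test the preset correlation between genes.

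Counts of paralogs (Apol9a and Apol9b, Mcpt1 and Mcpt2, the granzyme cluster, the Klra genes, Ifit3 and Ifit3b) and of overlapping genes are uncertain, since reads that match several genes can be split or dropped. Without a known strand setting, reads of a gene and of an antisense partner cannot be told apart.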

Results

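RNA was sequenced from mouse CD8 T cells, the lymphocytes that kill infected and transformed cells, which were taken from C57BL/6 spleen and cultured for 7 days. All cultures received interleukins IL-2 and IL-15, which keep activated CD8 T cells alive and dividing. All-trans retinoic acid (RA), the vitamin A metabolite that acts through nuclear receptors, and transforming growth factor beta (TGFβ), a cytokine that signals through SMAD proteins, were added alone, together or not at all. This gave 4 groups of 3 samples, named here IL-2 + IL-15, RA, TGFβ and TGFβ + RA. The series title states that the aim was to make tissue-resident memory CD8 T cells, which stay in tissues and do not recirculate, in culture. The labels call the samples biological replicates but do not say whether a replicate number is one animal, so p-values measure the spread between these samples only. Each library held 18300206 to 33477037 counts assigned to genes, with 14009 genes kept for testing. Unless stated otherwise, values are log2 fold changes ± SE or mean CPM (counts scaled to a common library size) ± SD, with n = 3 per group, and adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Each SE is derived from the F statistic and can understate the error where a group has few counts, as for many of the largest fold changes.

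The 4 groups separated on the first 2 principal components of log2 CPM, which carried 49.4% and 31.3% of the variance. On the first component the IL-2 + IL-15 and RA libraries lay between -55.4 and -27.8, the TGFβ libraries between 16.6 and 18.5, and the TGFβ + RA libraries between 66.9 and 70.7. The second component placed the RA and TGFβ + RA libraries between 25.6 and 43.7 and the other libraries between -54.6 and -13.0. Genes of the CD8 T cell were expressed in every group, with Cd8a, a chain of the co-receptor, at 1191 ± 175 CPM in IL-2 + IL-15, 1007 ± 169 in RA, 2452 ± 34.2 in TGFβ and 3070.0 ± 66.0 in TGFβ + RA. The share of counts from ribosomal protein genes was 8.05% ± 0.27 in IL-2 + IL-15, 8.44% ± 0.61 in RA, 5.15% ± 0.12 in TGFβ and 4.57% ± 0.32 in TGFβ + RA. An exact two-sided permutation test of this share gave p = 0.1, the smallest that 3 against 3 samples allow, for TGFβ and for TGFβ + RA against IL-2 + IL-15, and p = 0.5 for RA against IL-2 + IL-15. The share of mitochondrial genes was 1.95% ± 0.14, 1.81% ± 0.07, 1.73% ± 0.06 and 1.37% ± 0.09 in the same order of groups, and that of the 50 highest genes 13.6% ± 0.10, 14.1% ± 0.57, 11.9% ± 0.03 and 11.9% ± 0.04. The same permutation test of these 2 shares also gave p = 0.1 for TGFβ and for TGFβ + RA against IL-2 + IL-15, with p = 0.2 and p = 0.4 for RA. Transcripts of myeloid cells such as neutrophils appeared in TGFβ + RA replicate 3, with 323 counts of Lyz2, 177 of S100a9 and 97 of S100a8, and each had 23 or fewer counts in any other library. The macrophage and monocyte genes Csf1r, Cd14 and Adgre1 had 6, 2 and 0 counts in TGFβ + RA replicate 3.

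**Figure D1:**
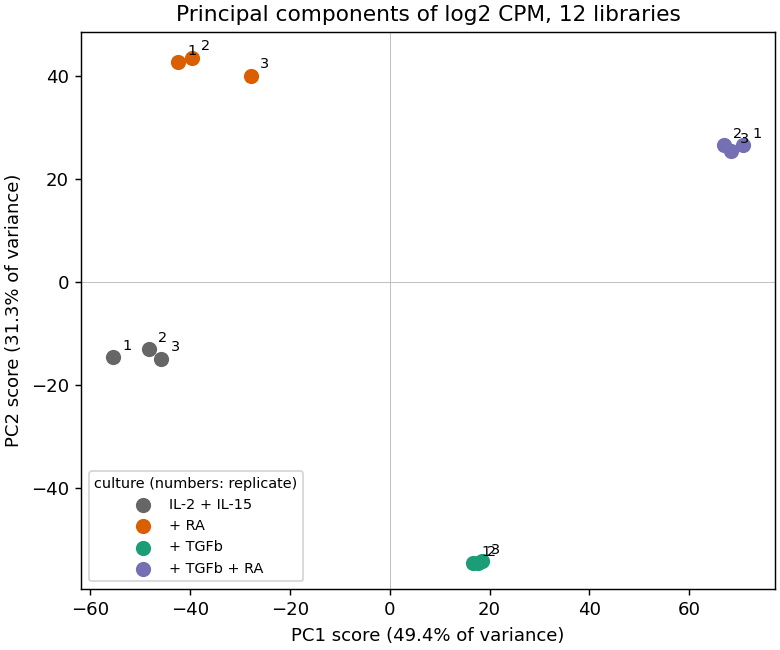
Scores of the 12 libraries on the first (horizontal) and second (vertical) principal component of log2 CPM, without unit, each point 1 library with its replicate number and colours for the 4 groups. TGFβ libraries lie at second component scores of -54.6 to -54.2 and RA libraries at 40.2 to 43.7.

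The first comparison, RA against IL-2 + IL-15, gives the effect of retinoic acid without added TGFβ. Ccr9, the chemokine receptor that guides T cells to the small intestine, rose from 4.0 ± 0.982 to 881 ± 173 CPM, a log2 fold change of 7.76 ± 0.19 (ENSMUSG00000029530, chromosome 9, 123678439 to 123784330, GRCm38). Itga4, the integrin α4 chain that pairs with Itgb7 in gut homing, rose by 2.58 ± 0.14, and Itgb7 rose by 0.29 ± 0.06. P2rx7, an ATP-gated ion channel, rose from 2.00 ± 0.354 to 611 ± 61.6 CPM (8.24 ± 0.17, ENSMUSG00000029468, chromosome 5, 122643911 to 122691432). These 4 genes were called at adjusted p of at most 0.00161 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and for each the 3 libraries with RA all lay above the 3 without it.

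Of the panel of 20 genes of residency, homing, egress and cytotoxicity, 10 rose with RA, 6 fell and 4 were not called. Residency genes that rose were Itgae, the integrin αE chain CD103 (0.92 ± 0.23), Itga1, the collagen-binding integrin CD49a (2.36 ± 0.26), the chemokine receptor Cxcr6 (1.16 ± 0.11), and the transcription factors Zfp683, also known as Hobit (2.56 ± 0.14), and Prdm1, also known as Blimp1 (0.81 ± 0.11). Egress and lymphoid genes fell, among them S1pr1, the receptor for exit into lymph and blood (-1.20 ± 0.11), its regulator Klf2 (-1.76 ± 0.29), Ccr7 (-1.37 ± 0.14) and Tcf7 (-1.0 ± 0.21). Tbx21, the transcription factor T-bet, and Gzma, which encodes granzyme A, rose by 0.58 ± 0.12 and 2.26 ± 0.32. Leaving out RA replicate 1 lowered the log2 fold change of Gzma to 1.63 (adjusted p = 6.7e-06 by edgeR's quasi-likelihood test). Cd69, an antagonist of S1pr1, was at 27.5 ± 2.21 CPM without and 26.7 ± 1.80 with RA (-0.04 ± 0.08, adjusted p = 0.779). Runx3 (-0.01 ± 0.07), Eomes (-0.39 ± 0.21) and Gzmb (0.43 ± 0.23) were not called, and Gzmb was called without RA replicate 3 (adjusted p = 0.00414, with 0.00191 to 0.631 over the alternatives but glmTreat). Ifng, which encodes interferon γ, fell by 2.68 (adjusted p = 0.0218), and its call was lost without IL-2 + IL-15 replicate 1, where the log2 fold change was -0.67 (0.199), RA replicate 1 (0.0582) or RA replicate 2 (0.0616), with the 9 libraries (0.268) and with only the 6 samples (0.0802), with 0.000222 to 0.268 over the alternatives but glmTreat. The call of Itgae (adjusted p = 0.00831) was lost when the fit used only the 6 samples (0.0526, with 2.5e-05 to 0.0526 over the alternatives but glmTreat). Against 1.5-fold by glmTreat the calls of Itgae, Prdm1, Itgb7, Tcf7, Tbx21 and Ifng were lost.

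Among the lists fixed in advance, residency genes moved upward with RA: 18 of 35 tested genes rose and 2 fell (18 and 3 adjusted over the list alone). These included Osgin1 (3.04), and the list had camera adjusted p = 2.5e-05, or 0.303 with an estimated correlation. Icos, a costimulatory receptor of the same list, fell (-1.62). Of the circulation and egress genes 2 of 24 tested genes rose and 18 fell (2 and 18 adjusted over the list alone), with camera adjusted p = 1.6e-07, and adjusted p = 0.303 with an estimated correlation; Elovl7 (-2.90) and Sidt1 (-1.03) were among those that fell. In the cytotoxic list 13 of 20 tested genes rose and 2 fell (14 and 2 adjusted over the list alone). These included Lamp1 (0.74), Srgn (0.66), Tnfsf10 (0.91) and Gzmc (4.06), and the list had camera adjusted p = 3.3e-05, or 0.5 with an estimated correlation. Cell cycle genes fell: of that list 1 of 30 tested genes rose and 25 fell (1 and 26 adjusted over the list alone). These included Foxm1 (-1.09), Rrm2 (-1.13) and Top2a (-0.83), and the list had camera adjusted p = 2.7e-10, or 0.386 with an estimated correlation. Of the interferon-stimulated genes 0 of 20 tested genes rose and 9 fell (0 and 10 adjusted over the list alone). These included Ifi44 (-1.60) and Usp18 (-1.16), and the list had camera adjusted p = 0.0088, or 0.854 with an estimated correlation.

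The other 19 tested lists were not called for RA. In the retinoid list 6 of 12 tested genes rose and 3 fell (6 and 3 adjusted over the list alone) (camera adjusted p = 0.0818); Dhrs3, a retinaldehyde reductase, rose by 5.45 ± 0.28, Hic1 by 4.87 ± 0.19 and Nrip1 by 1.71 ± 0.09, and the receptor gene Rarg fell by 1.66. Gut homing genes had 4 of 7 higher and 1 lower (camera adjusted p = 0.059, and 0.0318 without RA replicate 2). Of the inhibitory receptors 8 of 15 tested genes rose and 4 fell (8 and 5 adjusted over the list alone), including Lag3 (0.90), Cd160 (1.57) and Entpd1 (1.66), with camera adjusted p = 0.0779, and 0.0180 without the filter on low counts. Integrins and adhesion genes gave camera adjusted p = 0.0972, 0.0486 without RA replicate 3, 0.0185 with the 9 libraries and 0.0410 without the filter. The largest increases under the naming rule were Sorcs2 (8.54 ± 0.26, 0.237 to 90.5 ± 22.2 CPM), then P2rx7 and Ccr9, Mmp9, which encodes a matrix metalloproteinase (6.50 ± 0.38), and Dhrs3. The largest decreases under that rule were Endou (-6.89 ± 0.33), Stac2 (-5.73 ± 0.13), the unnamed gene RP24-353A8.2 (-5.53 ± 0.45), the interleukin receptor gene Il6ra (-5.23 ± 0.36) and Fut7, a fucosyltransferase that makes selectin ligands (-4.97 ± 0.15). Across all genes RA called 3740, of which 1731 were higher and 2009 lower, and 877 changed by at least 2-fold (343 higher and 534 lower). Of the bases in Ccr9 exons 18.8% are also annotated on the opposite strand, and the strand setting of the counting was not given in the sources used here.

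**Figure D2:**
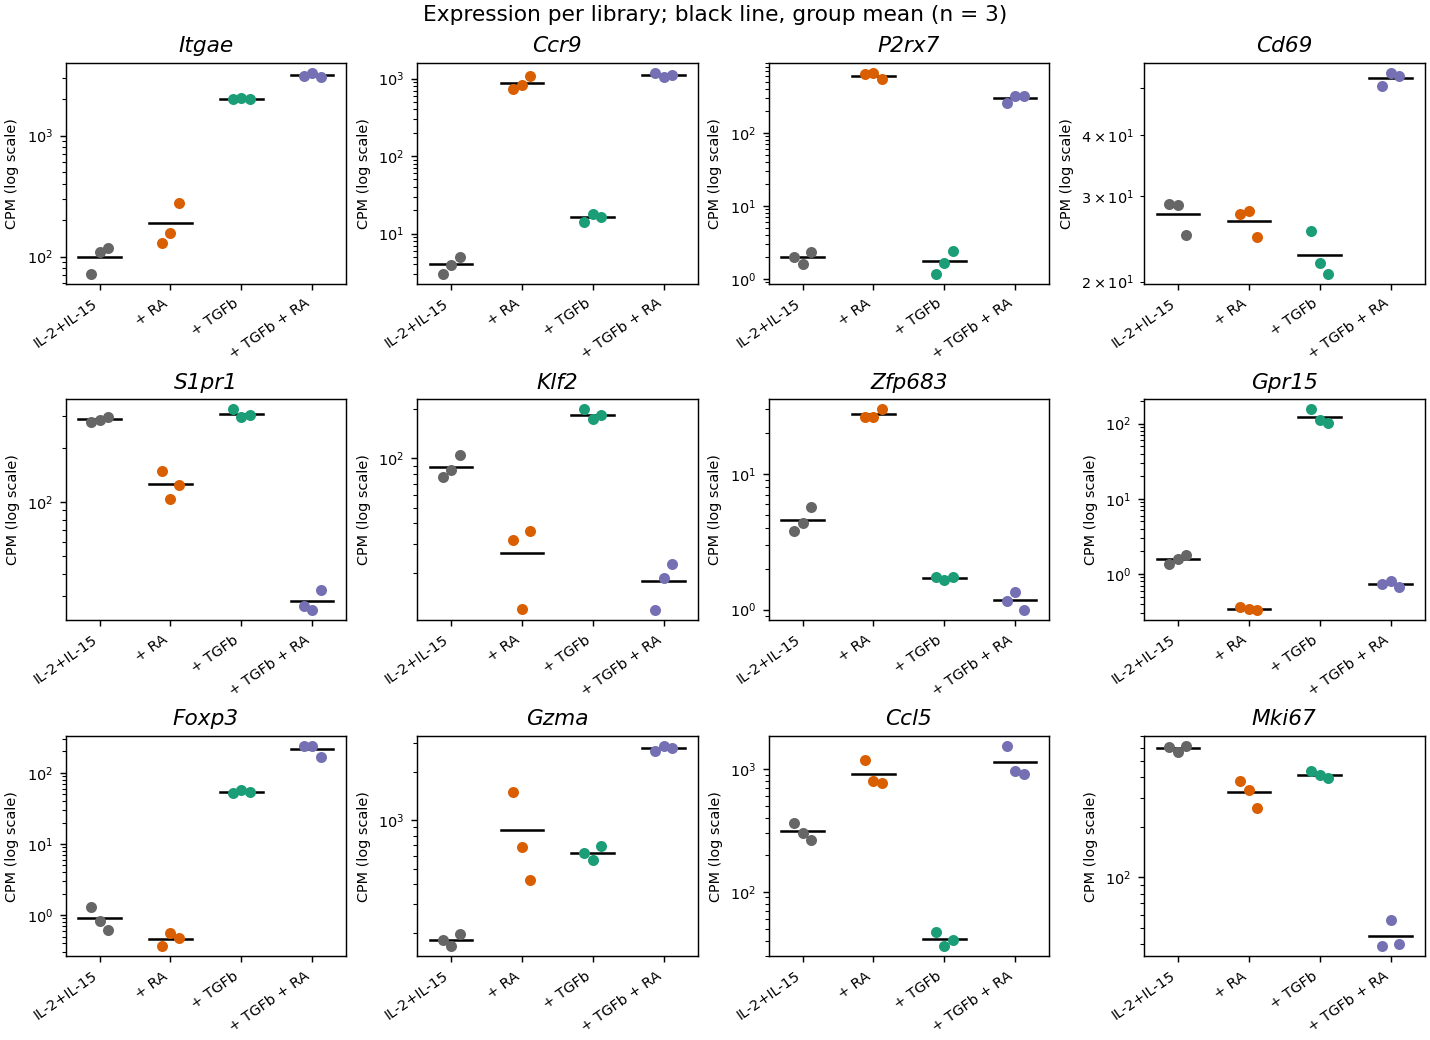
CPM on a log axis for Itgae, Ccr9, P2rx7, Cd69, S1pr1, Klf2, Zfp683, Gpr15, Foxp3, Gzma, Ccl5 and Mki67 in the 4 groups along the horizontal axis, each point 1 library and each black line the mean of 3. Ccr9 was at 881 ± 173 CPM in RA and 1112 ± 61.8 in TGFβ + RA, against 4.0 ± 0.98 in IL-2 + IL-15, and Itgae was at 2028 ± 30.9 in TGFβ and 3158 ± 121 in TGFβ + RA.

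TGFβ against IL-2 + IL-15 gives the effect of TGFβ without added RA. Itgae rose from 99.5 ± 23.9 to 2028 ± 30.9 CPM, a log2 fold change of 4.35 ± 0.25 (ENSMUSG00000005947, chromosome 11, 73090583 to 73147446). Genes of TGFβ feedback rose, with Ldlrad4 at 9.72 ± 0.245 against 142 ± 1.47 CPM (3.87 ± 0.08), Pmepa1 at 2.91 ± 0.07 and Skil at 1.93 ± 0.06. Foxp3, the transcription factor of regulatory T cells, rose from 0.914 ± 0.361 to 54.3 ± 2.48 CPM (5.91 ± 0.20, ENSMUSG00000039521, chromosome X, 7573644 to 7595245). Genes that fell included Prf1, which encodes perforin (-3.49 ± 0.32), Gzmb (-1.21 ± 0.23), the chemokine Ccl5 (-2.92 ± 0.22) and Tbx21 (-1.5 ± 0.12). These genes were called at adjusted p of at most 8.6e-04 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with no overlap between the 3 libraries of one group and the 3 of the other.

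Within the panel, 7 genes rose with TGFβ, 7 fell and 6 were not called. Besides Itgae, increases were measured for Runx3 (0.63 ± 0.07), Prdm1 (0.69 ± 0.11), Ccr9 (1.99 ± 0.19), Itgb7 (0.57 ± 0.06), Gzma (1.79 ± 0.31) and Klf2 (1.05 ± 0.27). Besides Tbx21 and Gzmb, decreases included those of Eomes (-1.84 ± 0.22), Zfp683 (-1.44 ± 0.17), Itga4 (-0.45 ± 0.13) and Cd69 (-0.27 ± 0.08). Values without a call were Itga1 (-0.23 ± 0.28), Cxcr6 (0.21 ± 0.11), S1pr1 (0.10 ± 0.11), Ccr7 (0.24 ± 0.14), Tcf7 (-0.22 ± 0.21) and Ifng (-0.53 ± 0.66), at adjusted p of 0.156 to 0.554 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With the replicate number as a block Cxcr6 was called (0.0312). The 9 libraries called Cxcr6 (0.0488) and Tcf7 (5.4e-05), and only the 6 samples in the fit called Ccr7 (0.0441). Without IL-2 + IL-15 replicate 1 the direction of Ifng turned, and it was called upward (1.46, adjusted p = 0.00328). The call of Cd69 (adjusted p = 0.0171) was lost without IL-2 + IL-15 replicate 1 (0.0624) or 2 (0.0624) and without TGFβ replicate 2 (0.0647) or 3 (0.0817), with 0.00407 to 0.0817 over the alternatives but glmTreat. That of Itga4 (adjusted p = 0.0142) was lost without IL-2 + IL-15 replicate 3 (0.0659, with 0.000509 to 0.0659 over the alternatives but glmTreat). With glmTreat against 1.5-fold Cd69, Prdm1, Runx3, Itga4, Itgb7 and Klf2 lost their calls.

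Of the 24 lists tested, 7 were called for TGFβ. Of the residency genes 22 of 35 tested genes rose and 9 fell (22 and 9 adjusted over the list alone). These included Nt5e, the ectonucleotidase CD73 (2.13), Hpgds (2.87), Cdh1, which encodes E-cadherin (5.80), and Adgrg1 (5.05), and the list had camera adjusted p = 5.9e-04, or 0.324 with an estimated correlation. Of the TGFβ pathway list 14 of 23 tested genes rose and 3 fell (14 and 3 adjusted over the list alone), and Smad3, which encodes a signal transducer of TGFβ, fell (-1.76), with camera adjusted p = 2.0e-04, and adjusted p = 0.23 with an estimated correlation. Glycolysis genes fell: of that list 0 of 18 tested genes rose and 17 fell (0 and 18 adjusted over the list alone). These included the glucose transporter Slc2a3 (-1.19), Hk2 (-1.16), Tpi1 (-0.76) and Ldha (-0.56), and the list had camera adjusted p = 9.9e-10, or 0.23 with an estimated correlation. Of the cholesterol and lipid genes 3 of 23 tested genes rose and 15 fell (3 and 15 adjusted over the list alone). These included Insig1 (-0.82) and Fasn (-0.77), while the cholesterol exporter Abca1 rose (1.86), and the list had camera adjusted p = 4.3e-04, or 0.467 with an estimated correlation. Of the cell cycle genes 0 of 30 tested genes rose and 21 fell (1 and 21 adjusted over the list alone). These included Mcm3 (-0.59) and Pcna (-0.44), and the list had camera adjusted p = 5.9e-04, or 0.683 with an estimated correlation. Of the interferon-stimulated genes 2 of 20 tested genes rose and 13 fell (3 and 13 adjusted over the list alone). These included Mx1 (-3.00), Mx2 (-2.98) and Ifi44 (-2.75), and the list had camera adjusted p = 0.00449, or 0.683 with an estimated correlation.

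Markers of myeloid and dendritic cells moved upward with TGFβ: 6 of 8 tested genes rose and 1 fell (6 and 1 adjusted over the list alone), and camera adjusted p = 0.00215, and adjusted p = 0.23 with an estimated correlation. The members that rose included genes of antigen presentation by MHC class II, with H2-Aa at 0.674 ± 0.310 against 27.0 ± 3.10 CPM (5.26 ± 0.34), H2-Eb1 (4.32 ± 0.20) and Cd74 (3.78 ± 0.27), and the transcription factor Zbtb46 (3.35 ± 0.24). In the same TGFβ libraries Csf1r, Cd14 and Clec9a, which mark macrophages, monocytes and dendritic cells, had 3 or fewer counts each and Flt3 had 6 or fewer, and Itgam was at 9.95 CPM before TMM scaling against 42.0 in IL-2 + IL-15. The other marker lists were not called. Of the B cell markers 3 of 5 tested genes rose and 1 fell (3 and 1 adjusted over the list alone) (camera adjusted p = 0.0861), and Ighm, the constant region gene of IgM, rose by 1.96 ± 0.15. Of the gamma delta T cell markers 4 of 5 tested genes rose and 1 fell (4 and 1 adjusted over the list alone) (camera adjusted p = 0.0861), of the CD4 T cell markers 1 of 4 tested genes rose and 3 fell (1 and 3 adjusted over the list alone) (camera adjusted p = 0.659) and of the NK cell markers 1 of 6 tested genes rose and 3 fell (1 and 3 adjusted over the list alone) (camera adjusted p = 0.485). Of the CD4 markers, Foxp3 rose while Cd4 (-1.75) and Zbtb7b (-1.12) fell, and the median of the list was -1.12 where its mean was 0.48. Of the erythroid and stromal markers 2 of 10 were tested, too few for a list test, and Col1a2 rose by 2.93 ± 0.79.

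Several lists held strong changes in both directions without a call for TGFβ. Of the cytotoxic genes 6 of 20 tested genes rose and 9 fell (6 and 10 adjusted over the list alone) (camera adjusted p = 0.624), with Serpinb9 among those that fell (-2.53). Of the cytokines and chemokines 5 of 16 tested genes rose and 4 fell (5 and 4 adjusted over the list alone) (camera adjusted p = 0.755), and Il10, which encodes an anti-inflammatory cytokine, rose from 0.512 ± 0.0207 to 24.8 ± 2.70 CPM (5.58 ± 0.24). Of the effector and memory transcription factors 14 of 35 tested genes rose and 14 fell (14 and 14 adjusted over the list alone) (camera adjusted p = 0.967); Ahr rose (4.39) and Nfil3 fell (-2.43). Of the cytokine receptors 5 of 23 tested genes rose and 7 fell (5 and 7 adjusted over the list alone) (camera adjusted p = 0.721). Of the NK receptors 8 of 21 tested genes rose and 8 fell (8 and 9 adjusted over the list alone) (camera adjusted p = 0.679), and of the immediate-early and stress genes 4 of 19 tested genes rose and 7 fell (5 and 7 adjusted over the list alone) (camera adjusted p = 0.967), with increases of Fos (2.68) and Jun (1.66). Integrins (8 higher, 11 lower of 23), inhibitory receptors (7 and 5 of 15) and CD8 identity genes (6 and 5 of 14) were not called. Skin homing genes, not called either, were called without the filter on low counts (0.0244). Among homing genes, Gpr15, a receptor for the colon, rose from 1.57 ± 0.215 to 122 ± 28.4 CPM (6.26 ± 0.17).

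The largest increase under the naming rule was Ace, which encodes angiotensin-converting enzyme, from 0.0921 ± 0.0448 to 102 ± 12.7 CPM (9.99 ± 0.18, ENSMUSG00000020681, chromosome 11, 105967945 to 105989964). Adcy5, an adenylate cyclase, rose by 8.15 ± 0.25 and Igha, the constant region gene of IgA, by 8.06 ± 0.20. The paralogs Apol9a and Apol9b, whose reads the counting could split, also led. Apol9a had 1033 counts in the TGFβ libraries against 2 in IL-2 + IL-15, a ratio of 600.1 with a 95% counting interval of 166 to 4962, and Apol9b rose by 8.26 ± 0.20. Under that rule the largest decreases were Adamts14 (-6.03 ± 0.53), Ccr2, a receptor for inflammatory chemokines (-4.84 ± 0.23), Ms4a4c (-3.65 ± 0.18), Igsf5 (-3.64 ± 0.39) and Klrb1c, the NK receptor NK1.1 (-3.52 ± 0.54). Of the exon bases of Foxp3 18.6% are shared with a gene on the same strand, and the corresponding shares were 13.9% for Klrb1c, 25.9% for Ifng and 31.2% for Igsf5, so these counts are uncertain. In all, 6034 genes were called, 2899 higher and 3135 lower, with 1288 changed by at least 2-fold (681 higher and 607 lower).

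**Figure D3:**
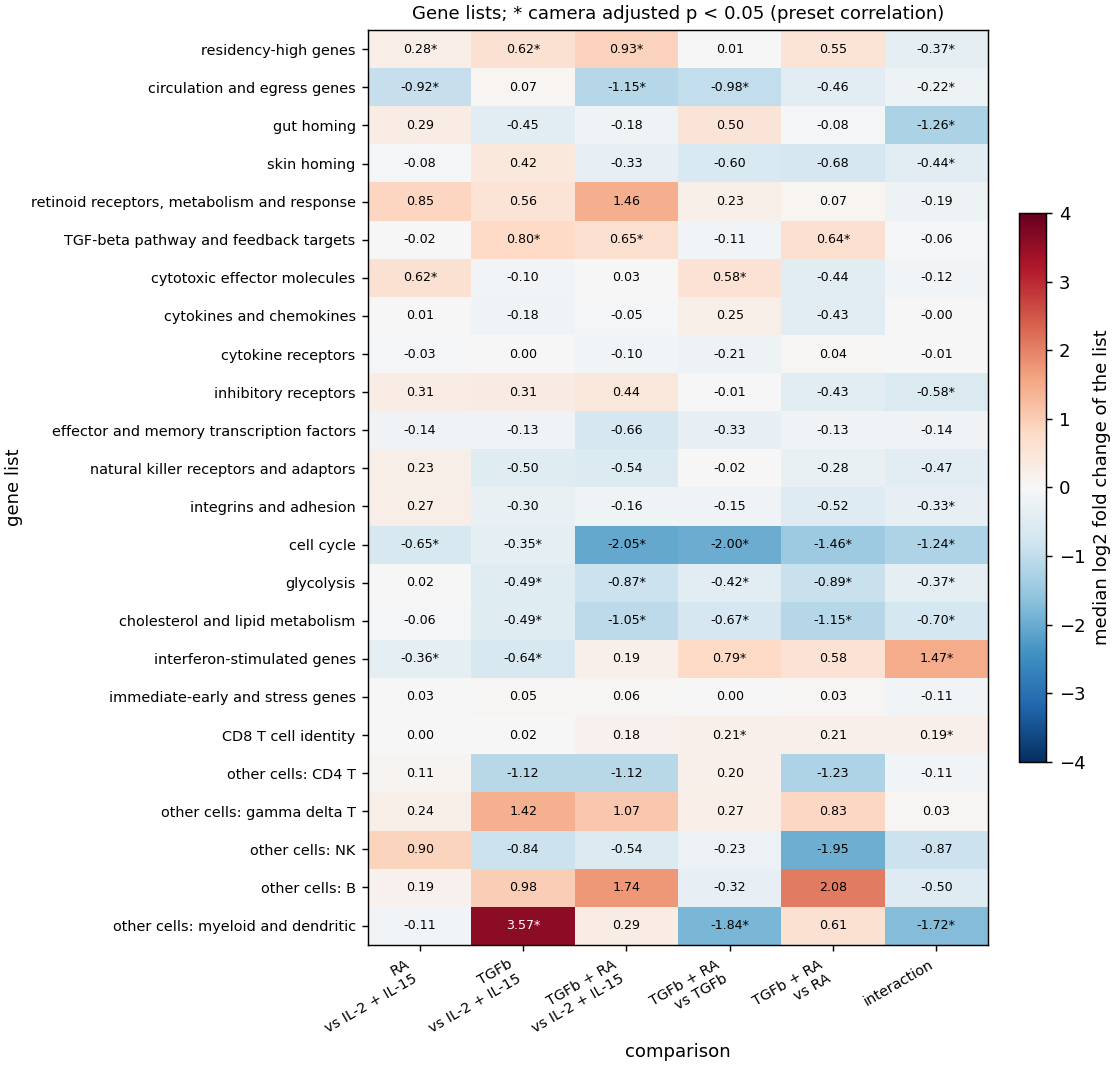
Median log2 fold change (number and colour, blue below 0 and red above) of each of the 24 tested gene lists, listed down the left side, in the 6 contrasts along the bottom, with an asterisk at camera adjusted p under 0.05. The cell cycle list has medians of -0.65 with RA and -2.05 with both factors, and the interferon-stimulated list has 1.47 in the interaction.

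TGFβ + RA against IL-2 + IL-15 gives the effect of both factors together. Itgae reached 3158 ± 121 CPM (4.99 ± 0.26), Ccr9 1112 ± 61.8 CPM (8.10 ± 0.19) and Gzma 2801 ± 94.2 CPM (3.95 ± 0.34). Cd69 rose from 27.5 ± 2.21 to 52.3 ± 1.70 CPM (0.93 ± 0.08), and S1pr1 fell from 288 ± 9.75 to 28.0 ± 3.96 CPM (-3.36 ± 0.12). Foxp3 rose to 214 ± 40.9 CPM (7.89 ± 0.20). The proliferation gene Mki67 fell from 596 ± 25.9 to 44.7 ± 9.44 CPM (-3.73 ± 0.15). Adjusted p was at most 3.1e-07 for these genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with no overlap between the 3 libraries of one group and the 3 of the other.

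Of the panel, 10 genes rose, 9 fell and 1 was not called. The other increases were Itga1 (2.22 ± 0.26), Cxcr6 (0.67 ± 0.11), Prdm1 (0.46 ± 0.11), Runx3 (0.43 ± 0.07), Itga4 (0.87 ± 0.13) and Itgb7 (0.25 ± 0.06). The other decreases included Zfp683 (-1.97 ± 0.18), Klf2 (-2.31 ± 0.30), Tcf7 (-0.74 ± 0.21), Eomes (-2.17 ± 0.23), Tbx21 (-1.01 ± 0.12), Gzmb (-1.55 ± 0.23) and Ifng (-4.56 ± 0.95). Without IL-2 + IL-15 replicate 1 Ifng was at -2.57 (adjusted p = 2.2e-04), and without TGFβ + RA replicate 1 at -5.48. Ccr7 was not called (-0.27 ± 0.14, adjusted p = 0.0999 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and was called without IL-2 + IL-15 replicate 1 (0.0304), without the filter on low counts (0.0299), with the 9 libraries (0.000197) and with only the 6 samples (0.0167), with 0.000197 to 0.266 over the alternatives but glmTreat. The calls of Cxcr6, Prdm1, Runx3, Itgb7 and Tcf7 were lost with glmTreat against 1.5-fold.

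With both factors, 6 lists were called. Of the residency genes 24 of 35 tested genes rose and 10 fell (24 and 10 adjusted over the list alone). These included P2rx7 (7.21), Hpgds (4.06) and Nt5e (2.60), and the list had camera adjusted p = 0.00115, or 0.295 with an estimated correlation. Of the circulation and egress genes 2 of 24 tested genes rose and 19 fell (2 and 19 adjusted over the list alone), with Ly6c2, a surface protein of effector and memory cells, at 1586 ± 124 against 90.6 ± 23.2 CPM (-4.12 ± 0.18), and camera adjusted p = 2.3e-05, and adjusted p = 0.295 with an estimated correlation. Of the TGFβ pathway list 14 of 23 tested genes rose and 5 fell (14 and 6 adjusted over the list alone). These included Ldlrad4 (3.91) and Pmepa1 (2.84) upward and the inhibitor of differentiation Id2 (-3.32) downward, and the list had camera adjusted p = 0.0165, or 0.295 with an estimated correlation. Cell cycle genes fell: of that list 0 of 30 tested genes rose and 29 fell (0 and 29 adjusted over the list alone). These included Top2a (-2.61), Foxm1 (-3.32) and Cdc6 (-4.23), and the list had camera adjusted p = 5.6e-14, or 0.295 with an estimated correlation. Of the glycolysis genes 0 of 18 tested genes rose and 16 fell (0 and 16 adjusted over the list alone). These included Hk2 (-2.12), Tpi1 (-1.59), Pgk1 (-1.53) and Ldha (-1.02), and the list had camera adjusted p = 4.2e-08, or 0.295 with an estimated correlation. Of the cholesterol and lipid genes 2 of 23 tested genes rose and 20 fell (2 and 20 adjusted over the list alone). These included Sqle (-1.83) and Scd2 (-1.64), and the list had camera adjusted p = 1.0e-06, or 0.295 with an estimated correlation.

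The other 18 lists were not called for both factors together. Of the effector and memory transcription factors 13 of 35 tested genes rose and 18 fell (13 and 18 adjusted over the list alone) (camera adjusted p = 0.592), with decreases of Batf3 (-4.35) and Irf4 (-1.73) beside the increase of Foxp3. Of the interferon-stimulated genes 9 of 20 tested genes rose and 6 fell (9 and 6 adjusted over the list alone) (camera adjusted p = 0.676), with Mx1 lower (-2.12). Of the integrins and adhesion genes 9 of 23 tested genes rose and 11 fell (9 and 11 adjusted over the list alone) (camera adjusted p = 0.754), with Cd44 (-2.28) and Itgal (-2.10) lower and Cd96 higher (1.76). CD8 identity genes were called without the filter on low counts (0.0268). The highest fold changes under the naming rule were the mast cell protease paralogs Mcpt1 (9.38 ± 0.73) and Mcpt2 (8.63 ± 0.63), whose reads the counting could split, Igha (8.49 ± 0.20) and Apol9b (8.49 ± 0.20). Apol9a had 941 counts against 2 in IL-2 + IL-15, a ratio of 530.4 with a 95% counting interval of 146 to 4386. The lowest under that rule were Endou (-8.14 ± 0.37), Stac2 (-7.42 ± 0.16), Ccr2 (-6.67 ± 0.26), Fut7 (-6.62 ± 0.18) and Wdr95 (-6.61 ± 0.41). In this comparison 8854 genes were called, 4314 higher and 4540 lower, of which 2581 changed by at least 2-fold (889 higher and 1692 lower).

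TGFβ + RA against TGFβ gives the effect of RA in cells that also received TGFβ. Ccr9 rose from 16.1 ± 2.08 to 1112 ± 61.8 CPM (6.11 ± 0.17) and P2rx7 from 1.76 ± 0.635 to 299 ± 36.1 CPM (7.41 ± 0.17). Cd69 rose from 22.7 ± 2.44 to 52.3 ± 1.70 CPM (1.21 ± 0.08), while S1pr1 (-3.47 ± 0.12) and Klf2 (-3.36 ± 0.30) fell. Ccl5 rose from 41.0 ± 5.52 to 1143 ± 351 CPM (4.80 ± 0.24), and Il10 fell from 24.8 ± 2.70 to 0.571 ± 0.223 CPM (-5.36 ± 0.24). Gpr15 fell from 122 ± 28.4 to 0.740 ± 0.0768 CPM (-7.35 ± 0.20, ENSMUSG00000047293, chromosome 16, 58717433 to 58719070). For these genes adjusted p was at most 9.6e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with no overlap between the 3 libraries of one group and the 3 of the other.

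In the panel, 8 genes rose, 7 fell and 5 were not called. Other increases were Itga1 (2.45 ± 0.26), Itga4 (1.32 ± 0.13), Gzma (2.16 ± 0.31), Tbx21 (0.49 ± 0.13), Cxcr6 (0.47 ± 0.11) and Itgae (0.64 ± 0.22). Other decreases included Ccr7 (-0.51 ± 0.14), Itgb7 (-0.33 ± 0.06), Runx3 (-0.20 ± 0.07) and Ifng (-4.03 ± 0.98), which was at -4.96 to -3.58 when single libraries were left out. Not called were Zfp683 (-0.53 ± 0.21), Prdm1 (-0.23 ± 0.11), Tcf7 (-0.52 ± 0.21), Eomes (-0.33 ± 0.23) and Gzmb (-0.34 ± 0.23), and Zfp683 (adjusted p = 0.0538 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) was called without TGFβ + RA replicate 2 (0.0479, with 0.0428 to 0.180 over the alternatives but glmTreat). With the replicate number as a block, Zfp683 (0.0474), Prdm1 (0.0373) and Tcf7 (0.0213) were called. The 9 libraries called Prdm1 (0.0447), Tcf7 (7.4e-07) and Eomes (0.0368), only the 6 samples in the fit called Zfp683 (0.0428), Prdm1 (0.00336), Tcf7 (1.6e-06) and Gzmb (0.0379), and Tcf7 was called without the filter (0.00436). The call of Itgae (adjusted p = 0.0302) was lost without TGFβ replicate 1 (0.0743), 2 (0.0675) or 3 (0.0775), without TGFβ + RA replicate 1 (0.0577), 2 (0.0765) or 3 (0.0582) and with DESeq2 (0.0593), with 4.2e-07 to 0.0775 over the alternatives but glmTreat. That of Runx3 (adjusted p = 0.031) was lost without TGFβ replicate 2 (0.0581) or 3 (0.115) and without TGFβ + RA replicate 1 (0.0580), 2 (0.0792) or 3 (0.0871), with 0.00111 to 0.115 over the alternatives but glmTreat. Itgae, Cxcr6, Runx3, Itgb7, Ccr7 and Tbx21 lost their calls with glmTreat against 1.5-fold.

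RA in the presence of TGFβ gave calls for 8 lists. Of the circulation and egress genes 0 of 24 tested genes rose and 18 fell (0 and 19 adjusted over the list alone). These included Ly6c2 (-3.05) and Elovl7 (-4.21), and the list had camera adjusted p = 1.7e-07, or 0.266 with an estimated correlation. Of the cytotoxic genes 12 of 20 tested genes rose and 1 fell (12 and 1 adjusted over the list alone). These included Serpinb6b (2.05), Serpinb9 (1.51) and Lamp1 (0.60), and the list had camera adjusted p = 0.00143, or 0.537 with an estimated correlation. Of the interferon-stimulated genes 15 of 20 tested genes rose and 0 fell (16 and 0 adjusted over the list alone). These included Oas2 (3.27), Mx2 (2.51) and Ifit1 (1.29), and the list had camera adjusted p = 1.5e-05, or 0.455 with an estimated correlation. Of the CD8 identity genes 8 of 14 tested genes rose and 1 fell (10 and 1 adjusted over the list alone). These included Cd3e (0.43), Cd3g (0.41) and Trbc2 (0.39), and the list had camera adjusted p = 0.0159, or 0.347 with an estimated correlation. Cell cycle genes fell: of that list 1 of 30 tested genes rose and 29 fell (1 and 29 adjusted over the list alone). These included Mki67 (-3.20), Foxm1 (-2.90) and Top2a (-2.19), and the list had camera adjusted p = 2.7e-17, or 0.266 with an estimated correlation. Of the glycolysis genes 1 of 18 tested genes rose and 13 fell (1 and 14 adjusted over the list alone). These included Hk2 (-0.96) and Tpi1 (-0.84), and the list had camera adjusted p = 1.7e-04, or 0.455 with an estimated correlation. Of the cholesterol and lipid genes 1 of 23 tested genes rose and 20 fell (1 and 20 adjusted over the list alone). These included Scd2 (-0.91), and the list had camera adjusted p = 1.2e-07, or 0.266 with an estimated correlation. Of the myeloid and dendritic markers 0 of 8 tested genes rose and 7 fell (0 and 7 adjusted over the list alone). These included Cd74 (-3.55), Zbtb46 (-3.09) and H2-Eb1 (-2.44), and the list had camera adjusted p = 0.00142, or 0.266 with an estimated correlation. TGFβ + RA replicate 3, which held the transcripts of myeloid cells such as neutrophils, is in this comparison.

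The remaining 16 lists were not called. Residency genes went both ways: 14 of 35 tested genes rose and 9 fell (14 and 11 adjusted over the list alone) (camera adjusted p = 0.546). Skin homing genes had 1 of 8 higher and 5 lower (camera adjusted p = 0.0591); Fut7 fell by 7.02 and Ccr4, a skin homing receptor, fell by 2.75. That list was called without IL-2 + IL-15 replicate 3 (0.0451), TGFβ + RA replicate 1 (0.0496) or TGFβ replicate 2 (0.0356), and without the filter on low counts (0.00996). Among transcription factors, Irf4 fell (-2.00) while Bcl6 (1.07) and Foxp3 (1.98) rose, and Pdcd1, the inhibitory receptor PD-1, fell (-2.53). Increases under the naming rule were led by P2rx7, Ccr9, Tgm2, a transglutaminase (5.93 ± 0.37), Sorcs2 (5.72 ± 0.25) and Grtp1 (5.01 ± 0.23). Decreases were led by Ace, from 102 ± 12.7 to 0.165 ± 0.0212 CPM (-9.22 ± 0.17), Endou (-8.64 ± 0.36), Stac2 (-7.89 ± 0.15), Gpr15 and Fut7. The calls numbered 6029, with 2843 higher, 3186 lower and 1596 changed by at least 2-fold (406 higher and 1190 lower). Of the exon bases of Gpr15 12.5% and of Tgm2 13.7% are annotated on the opposite strand too.

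TGFβ + RA against RA gives the effect of TGFβ in cells that also received RA. Itgae rose from 188 ± 78.8 to 3158 ± 121 CPM (4.07 ± 0.25), and Foxp3 from 0.468 ± 0.10 to 214 ± 40.9 CPM (8.80 ± 0.22). Zfp683 fell from 27.4 ± 2.07 to 1.17 ± 0.178 CPM (-4.53 ± 0.16), and S1pr1 fell from 126 ± 22.0 to 28.0 ± 3.96 CPM (-2.17 ± 0.12). Mmp9 (-7.03 ± 0.41) and Ccr2 (-6.72 ± 0.26) fell the most under the naming rule, followed by Epas1, which encodes a hypoxia-inducible factor (-6.24 ± 0.39), Tnfrsf8, the receptor CD30 (-5.41 ± 0.19), and Wdr95 (-5.31 ± 0.45). Adjusted p of these genes was at most 3.3e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with no overlap between the 3 libraries of one group and the 3 of the other.

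Of the panel, 6 genes rose, 8 fell and 6 were not called. Besides Itgae, increases were measured for Gzma (1.69 ± 0.31), Ccr7 (1.10 ± 0.14), Cd69 (0.97 ± 0.08), Runx3 (0.44 ± 0.07) and Ccr9 (0.34 ± 0.13). Besides Zfp683 and S1pr1, decreases were measured for Gzmb (-1.98 ± 0.24), Eomes (-1.78 ± 0.23), Itga4 (-1.71 ± 0.13), Tbx21 (-1.59 ± 0.12), Cxcr6 (-0.49 ± 0.11) and Prdm1 (-0.35 ± 0.11). The log2 fold change of Gzma was 1.36 to 2.31 when single libraries were left out. The call of Ccr9 (adjusted p = 0.0363 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) was lost without RA replicate 1 (0.176) or 2 (0.136), without TGFβ + RA replicate 1 (0.105) or 3 (0.0713), with DESeq2 (0.110) and with only the 6 samples (0.0524), with 0.000341 to 0.176 over the alternatives but glmTreat. With glmTreat against 1.5-fold the calls of Ccr9, Cxcr6, Prdm1 and Runx3 were lost. Genes not called included Itga1 (-0.14 ± 0.23), Itgb7 (-0.04 ± 0.06), Klf2 (-0.54 ± 0.31), Tcf7 (0.26 ± 0.21) and Ifng (-1.89 ± 1.16), which was at -2.81 to -1.44 when single libraries were left out. Leaving out 1 library called Itga1 (RA replicate 3, adjusted p = 0.0202, with 0.00709 to 0.852 over the alternatives but glmTreat), Klf2 (RA replicate 2, 0.00173, with 0.00173 to 0.473) and Tcf7 (RA replicate 3, 5.9e-05, with 4.1e-07 to 0.792). Klf2 was called without the filter (0.0421), and Ifng with the 9 libraries (0.00557) and with only the 6 samples (0.0147).

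Here 4 lists were called. Of the TGFβ pathway list 13 of 23 tested genes rose and 5 fell (13 and 5 adjusted over the list alone). These included Ldlrad4 (3.64), Pmepa1 (3.36) and Skil (1.85) upward and Smad3 (-1.76) downward, and the list had camera adjusted p = 0.0116, or 0.392 with an estimated correlation. Cell cycle genes fell: of that list 0 of 30 tested genes rose and 29 fell (0 and 29 adjusted over the list alone). These included Cdc6 (-3.27) and Mki67 (-2.85), and the list had camera adjusted p = 5.4e-12, or 0.459 with an estimated correlation. Of the glycolysis genes 0 of 18 tested genes rose and 17 fell (0 and 17 adjusted over the list alone). These included Hk2 (-2.14), Tpi1 (-1.66) and Gapdh (-1.30), and the list had camera adjusted p = 4.2e-09, or 0.392 with an estimated correlation. Of the cholesterol and lipid genes 2 of 23 tested genes rose and 18 fell (2 and 18 adjusted over the list alone). These included Scd2 (-1.58), and the list had camera adjusted p = 1.9e-07, or 0.392 with an estimated correlation. Residency genes had 20 higher and 12 lower of 35 (camera adjusted p = 0.0745), and leaving out IL-2 + IL-15 replicate 1 (0.0381) or 2 (0.0488) or RA replicate 1 (0.0212) or 2 (0.0344) called that list. Circulation and egress genes had 2 higher and 12 lower of 24 (camera adjusted p = 0.144, and 0.0236 without RA replicate 2). Interferon-stimulated genes had 12 higher and 3 lower of 20 (camera adjusted p = 0.103, 0.0346 without RA replicate 1 and 0.00831 without TGFβ + RA replicate 1). Without the filter on low counts the lists of residency (0.0223), circulation and egress (0.0386), interferon-stimulated (0.0336), CD8 identity (0.0336) and integrin genes (0.0404) were called. Genes with the highest fold changes under the naming rule were Mcpt1 (9.75 ± 0.78), Foxp3, Apol9b (8.72 ± 0.21) and Mcpt2 (8.26 ± 0.63), and Apol9a had 941 counts against 3, a ratio of 297 with a 95% counting interval of 101 to 1442. The comparison called 8440 genes, 4124 higher and 4316 lower, of which 2355 changed by at least 2-fold (909 higher and 1446 lower).

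The interaction asks whether the effect of one factor differed with the other, as the log2 fold change of TGFβ + RA against TGFβ minus that of RA against IL-2 + IL-15. A higher or lower RA effect is meant with its sign, so a lower one can be a larger fall or a smaller rise. Cd69 had an interaction of 1.24 ± 0.12: RA left it at -0.04 without TGFβ and raised it by 1.21 with TGFβ. S1pr1 had -2.27 ± 0.16, RA values of -1.20 without TGFβ and -3.47 with it. Zfp683 had -3.09 ± 0.25, with RA values of 2.56 without TGFβ and -0.53 with it. Mki67 had -2.32 ± 0.19, with RA values of -0.88 and -3.20. Ccl5 had 3.23 ± 0.30, with 1.57 without TGFβ and 4.80 with it. The adjusted p of these 5 genes was at most 1.0e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

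Of the panel, 3 genes had a higher RA effect with TGFβ than without it, 8 a lower one and 9 no call. The higher ones included Ccr7 (0.86 ± 0.20) besides Cd69. The lower ones besides S1pr1 and Zfp683 were Ccr9 (-1.66 ± 0.23), Klf2 (-1.60 ± 0.41), Itga4 (-1.26 ± 0.19), Prdm1 (-1.05 ± 0.15), Cxcr6 (-0.70 ± 0.16) and Itgb7 (-0.61 ± 0.08). Itgae (-0.28 ± 0.31), Itga1 (0.09 ± 0.36), Runx3 (-0.19 ± 0.10), Eomes (0.06 ± 0.31), Tbx21 (-0.10 ± 0.17), Gzma (-0.10 ± 0.43), Tcf7 (0.48 ± 0.29), Gzmb (-0.77 ± 0.32) and Ifng (-1.36 ± 1.35) were not called. Leaving out RA replicate 3 called Tcf7 (adjusted p = 0.000232 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 7.3e-07 to 0.544 over the alternatives but glmTreat) and Gzmb (0.00262, with 0.00173 to 0.261), and leaving out IL-2 + IL-15 replicate 1 called Ifng (0.000887, with 0.000715 to 0.737) and moved its value to -3.36. The value of Gzma was -0.44 to 0.52 when single libraries were left out, and it was not called in any of these fits. Gzmb was called without the filter (0.0168) and Tbx21 with the 9 libraries (0.0171). Against 1.5-fold by glmTreat Cxcr6, Itgb7, Klf2 and Ccr7 lost their calls.

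The interaction called 12 lists, 10 with a lower and 2 with a higher RA effect in the presence of TGFβ. The interferon-stimulated genes had 17 of 20 higher and 0 lower (19 and 0 adjusted over the list alone). These included Usp18 (2.32 ± 0.27) and Ifi44 (3.02 ± 0.43), and the list had camera adjusted p = 4.7e-11, or 0.181 with an estimated correlation. CD8 identity genes had 5 of 14 higher and 0 lower (7 and 0 adjusted over the list alone). These included Lat (0.45) and Trbc1 (0.30), and the list had camera adjusted p = 0.00532, or 0.181 with an estimated correlation. Cell cycle genes had 0 higher and 25 lower of 30 (0 and 27 adjusted over the list alone). These included Cdc20 (-2.19), and the list had camera adjusted p = 2.5e-15, or 0.181 with an estimated correlation. Cholesterol and lipid genes had 1 higher and 19 lower of 23 (1 and 19 adjusted over the list alone). These included Scd2 (-0.85), and the list had camera adjusted p = 4.7e-11, or 0.18 with an estimated correlation. Glycolysis genes had 0 higher and 11 lower of 18 (1 and 12 adjusted over the list alone). These included Hk2 (-0.98) and Tpi1 (-0.90), and the list had camera adjusted p = 9.9e-06, or 0.193 with an estimated correlation. Residency genes had 3 higher and 14 lower of 35 (4 and 17 adjusted over the list alone). These included Cd101 (-0.94) and Nt5e (-0.76), and the list had camera adjusted p = 0.0058, or 0.223 with an estimated correlation. Integrins and adhesion genes had 0 higher and 11 lower of 23 (0 and 12 adjusted over the list alone). These included Cd44 (-1.52) and Itgal (-1.12), and the list had camera adjusted p = 5.5e-04, or 0.181 with an estimated correlation. Inhibitory receptors had 0 higher and 9 lower of 15 (0 and 10 adjusted over the list alone). These included Pdcd1 (-2.21), and the list had camera adjusted p = 0.00163, or 0.18 with an estimated correlation. Myeloid and dendritic markers had 0 higher and 5 lower of 8 (0 and 5 adjusted over the list alone). These included H2-Eb1 (-3.47) and Zbtb46 (-3.00), and the list had camera adjusted p = 9.7e-04, or 0.18 with an estimated correlation.

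The calls of the last 3 lists changed when 1 library was left out. Gut homing genes had 2 higher and 5 lower of 7 (2 and 5 adjusted over the list alone), with camera adjusted p = 0.0114, and adjusted p = 0.181 with an estimated correlation, and the call was lost without RA replicate 3 (0.0540) and with the 9 libraries (0.0784). Skin homing genes had 1 higher and 3 lower of 8 (1 and 3 adjusted over the list alone). These included Ccr4 (-2.65) and Fut7 (-2.05), and the list had camera adjusted p = 0.0323, or 0.305 with an estimated correlation, and the call was lost without IL-2 + IL-15 replicate 2 (0.0573) or RA replicate 1 (0.0906). Circulation and egress genes had 3 higher and 10 lower of 24 (3 and 10 adjusted over the list alone). These included Ly6c2 (-1.91) and Il7r (-1.05), and the list had camera adjusted p = 0.0443, or 0.581 with an estimated correlation. That call was lost without IL-2 + IL-15 replicate 1 (0.0949) or 2 (0.0583), RA replicate 1 (0.111) or 3 (0.317), TGFβ replicate 1 (0.0530) or TGFβ + RA replicate 1 (0.0673), with the replicate number as a block (0.0917) and with the 9 libraries (0.373). NK cell markers were not called (camera adjusted p = 0.147), and were called without IL-2 + IL-15 replicate 1 (0.0450), with the 9 libraries (0.0301) and without the filter on low counts (0.0358). Effector and memory transcription factors were called without that filter (0.0456). Among transcription factors Irf4 had -1.64 ± 0.06 and Bcl6 1.15 ± 0.08. Under the naming rule, with a mean of at least 5 CPM, the highest interaction values were Heatr9 (3.26 ± 0.24), Ccl5, Oas2 (2.98 ± 0.60), Foxp3 (2.89 ± 0.46) and Dtx1 (2.78 ± 0.29), and the lowest Ace (-10.25 ± 0.75), Gja5 (-5.71 ± 0.74), Gpr15 (-5.16 ± 0.65), Itsn1 (-5.14 ± 0.40) and Agap1 (-4.88 ± 0.48).

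The interaction was called for 2702 genes, 974 higher and 1728 lower, and for 4158 when RA replicate 3 was left out. Leaving out each library in turn gave 583 to 1654 higher and 1383 to 2504 lower genes, and glmTreat against 1.5-fold gave 83 higher and 503 lower. For 164 of the called genes RA gave a call upward both without and with TGFβ and for 559 a call downward in both. RA raised 117 of them without TGFβ and lowered them with it, 63 went the other way, and 544 were called higher and 789 lower with TGFβ and not called without it. A further 204 were called higher and 170 lower without TGFβ and not called with it, and 92 were called in neither. Over all 14009 genes, the RA effects without and with TGFβ had a Pearson correlation of 0.585 (jackknife SE 0.070 over libraries) and a Spearman correlation of 0.451, across genes, which are not independent replicates. Both effects were called upward for 944 genes, against 351 for independent lists, and both downward for 1414, against 457. The TGFβ effects without and with RA had a Pearson correlation of 0.702 (jackknife SE 0.038) and a Spearman correlation of 0.690. Without the filter on low counts these Pearson correlations were 0.232 and 0.363, and with the 9 libraries 0.485 and 0.638. The effects in each of these pairs share no library. The average RA effect and the average TGFβ effect had a Pearson correlation of 0.127 (jackknife SE 0.067) and a Spearman correlation of 0.204.

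**Figure D4:**
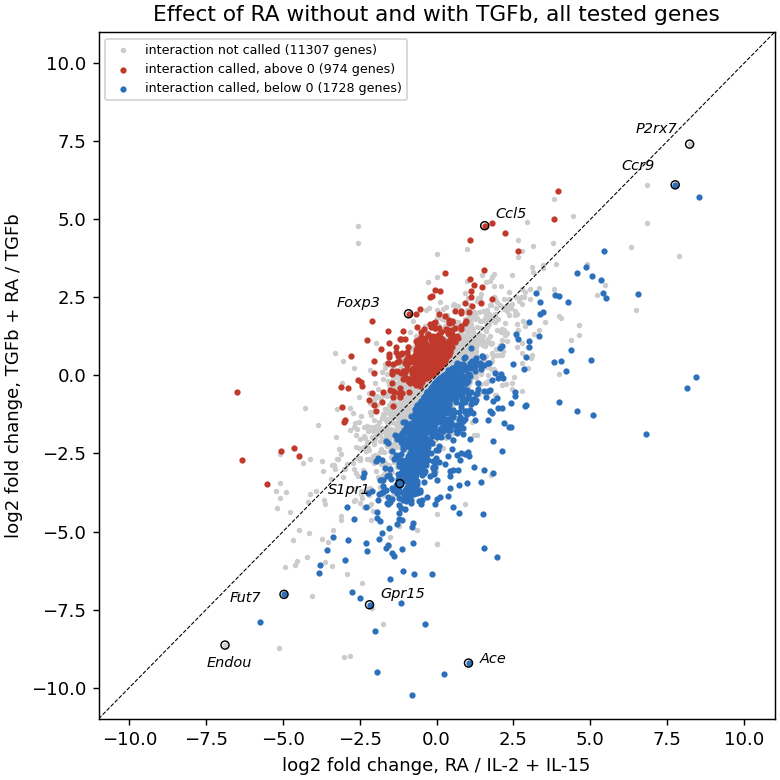
Log2 fold change of RA against IL-2 + IL-15 (horizontal) and of TGFβ + RA against TGFβ (vertical), each point 1 of 14009 genes, red where the interaction was called above 0, blue where it was called below 0 and grey otherwise, with the line of equal effects dashed. Ccl5 lies above the line (1.57 without and 4.80 with TGFβ), and S1pr1 (-1.20 and -3.47) and Ace (1.04 and -9.22) lie below it.

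In the list tests, camera compared each list with all other genes under a preset correlation between genes, and 0 of the calls held with an estimated correlation in any of the 6 contrasts. At an unadjusted p under 0.05 with that estimate, camera gave 3, 3, 1, 4, 3 and 4 lists in the order of the comparisons above. The rotation test fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, called 10, 15, 18, 17, 19 and 17 lists in the same order. Median, mean and camera direction differed in sign for 9, 7, 5, 3, 4 and 3 lists, and for 0 of the called lists.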

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

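The comparison of Foxp3 with Cd4 was a test chosen only after the result was seen; the interaction tests and the count of other groupings were planned. The results here were singled out because the RA effect differed with and without TGFβ by a test of that difference, the interaction of edgeR's quasi-likelihood model. Values are the interaction on the log2 scale, so that a positive value means a higher RA effect in the presence of TGFβ. The effect is taken with its sign, so a lower one can be a larger fall, a smaller rise or a turn of direction. The real grouping gave 2702 interaction genes and the highest of the other groupings of the 12 libraries into 4 groups of 3 gave 1626, and 1 of 100 groupings, the real one, gave as many. At an unadjusted p under 0.05 the real grouping gave 4661 genes and the highest other 5502. Regrouping puts the effects of RA and of TGFβ into the residual spread, which lowers the calls of the other groupings whether or not there is an interaction, so this count does not settle whether chance can be excluded. Without RA replicate 3 the count was 4158.

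Among genes of residency and homing, RA effects were higher with TGFβ for Cd69 (1.24) and Ccr7 (0.86) and lower for Zfp683 (-3.09), S1pr1 (-2.27), Ccr9 (-1.66), Klf2 (-1.60), Itga4 (-1.26), Prdm1 (-1.05), Cxcr6 (-0.70) and Itgb7 (-0.61). The circulation genes Ly6c2 (-1.91) and Il7r (-1.05), the residency genes Cd101 (-0.94) and Nt5e (-0.76), the skin homing genes Ccr4 (-2.65) and Fut7 (-2.05) and the inhibitory receptor Pdcd1 (-2.21) were lower as well. The medians of these lists were -0.37 for residency, -0.22 for circulation and egress, -1.26 for gut homing, -0.44 for skin homing and -0.58 for inhibitory receptors. Of the list calls, that of circulation and egress (adjusted p = 0.0443 by camera) was lost in 8 of 16 settings besides the estimated correlation, which kept none. It was at 0.0917 with the replicate number as a block and reached 0.373 with the 9 libraries. The call of gut homing was lost in 2, reaching 0.0784, and that of skin homing in 2, reaching 0.0906.

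Genes of proliferation and metabolism had lower RA effects with TGFβ: Mki67 (-2.32) and Cdc20 (-2.19) of the cell cycle (list median -1.24), Hk2 (-0.98) and Tpi1 (-0.90) of glycolysis (-0.37) and Scd2 (-0.85) of the cholesterol and lipid list (-0.70). For Mki67 this was a larger fall: RA lowered it without TGFβ, and by more with it. In the integrin and adhesion list (-0.33) the genes with lower RA effects included Cd44 (-1.52) and Itgal (-1.12). The interferon-stimulated genes Usp18 (2.32) and Ifi44 (3.02) and their list (1.47) had higher RA effects with TGFβ, as did Lat (0.45) and Trbc1 (0.30) of the CD8 identity list (0.19). Of the myeloid and dendritic markers (-1.72), H2-Eb1 (-3.47) and Zbtb46 (-3.00) were lower. The transcription factor Irf4 (-1.64) was lower and Bcl6 (1.15) higher. Under the naming rule, with a mean of at least 5 CPM, the largest values were those of Heatr9 (3.26), Ccl5 (3.23), Oas2 (2.98), Foxp3 (2.89) and Dtx1 (2.78) upward and Ace (-10.25), Gja5 (-5.71), Gpr15 (-5.16), Itsn1 (-5.14) and Agap1 (-4.88) downward.

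Foxp3 was nearly absent from IL-2 + IL-15 and RA, at 0.914 and 0.468 CPM, and reached 54.3 in TGFβ and 214 in TGFβ + RA. CD4 T cells that became regulatory cells, carried over from the spleen, were one technical explanation tested. They would bring Cd4 with Foxp3, yet the highest Cd4 count was 0.441% of the Foxp3 count in any TGFβ + RA library, and Cd4 was lower in TGFβ (0.403 CPM before TMM scaling) and TGFβ + RA (0.476) than in IL-2 + IL-15 (1.32), which argues against that source. Expression of Foxp3 by the CD8 T cells themselves was not tested and stays open as a hypothesis, which counts from whole cultures do not decide and a measurement of Foxp3 in single CD8 T cells would. Reads of Flicr, which shares 18.6% of the exon bases of Foxp3 on the same strand, stay open too. So do reads of the opposite strand, where Ccdc22, Gm36995 and Ppp1r3f share 12.9%, 8.15% and 5.81% of these bases, since the strand setting is not known.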

How the results depend on the processing

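The fit to the 9 libraries and the genes that mark replicate numbers were tests chosen only after the data were seen. With glmTreat against 1.5-fold, which tests a larger change by construction, the calls fell to 637 for RA, 1225 for TGFβ, 2903 for TGFβ + RA against IL-2 + IL-15, 1546 for TGFβ + RA against TGFβ, 2503 for TGFβ + RA against RA and 586 for the interaction. Leaving out each library in turn gave 2040 to 4158 interaction genes, the highest without RA replicate 3. Of these, 583 to 1654 had a higher RA effect, against 974 in the main fit. The 9 libraries, whose groups differ in replicate number, gave 4224, with 1718 higher. No other setting moved a total count of genes by over 1.5 times: DESeq2 size factors gave 3762, 6043, 8860, 6044, 8459 and 2704 in the same order, and the Wald test of DESeq2 gave 3727, 5821, 8541, 5822, 8146 and 2897. Only the 6 samples in the fit gave 2611, 6275, 8813, 6757 and 7704. None of the genes called both in the main analysis and in an alternative changed direction.

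Without the filter on low counts the correlation of the RA effects without and with TGFβ was 0.232, and that of the TGFβ effects without and with RA was 0.363, with 23785 genes in place of 14009. With the 9 libraries these correlations were 0.485 and 0.638, and leaving out each library gave 0.662 to 0.707 for the TGFβ effects. The cause was not tested for any of these. Camera with an estimated correlation called 0 lists in each contrast (3, 3, 1, 4, 3 and 4 at an unadjusted p under 0.05), and fry, which is another kind of test, called 10, 15, 18, 17 and 19 lists for the 5 comparisons of 2 groups. Lists that camera did not call were called by fry in the other direction for TGFβ (gut homing and CD4 T cell markers, both with an adjusted p of 0.00286), for TGFβ + RA against IL-2 + IL-15 (CD4 T cell markers, 1.2e-05) and for TGFβ + RA against RA (retinoid genes, 0.0222, cytokine receptors, 0.00604, and CD4 T cell markers, 1.9e-05), and the cause was not tested. Without the filter 9 lists were called for TGFβ + RA against RA.

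Of the named genes, 102 were called for RA, and 61 of these kept their call in every setting, 31 lost it only against 1.5-fold and 10 elsewhere. The same counts were 113, 85, 23 and 5 for TGFβ, 115, 100, 14 and 1 for TGFβ + RA against IL-2 + IL-15, 107, 83, 17 and 7 for TGFβ + RA against TGFβ, 108, 94, 12 and 2 for TGFβ + RA against RA, and 90, 54, 27 and 9 for the interaction, and 0 of the called genes reversed. Ifng, which was not called for TGFβ (-0.53), was at -0.99 to 1.46 when each library was left out. It was called in the other direction without IL-2 + IL-15 replicate 1 (1.46) and with the 9 libraries (1.46), and the cause was not tested.

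The replicate numbers did not pair the samples by the fixed rule, since 3 of 6 pairs of groups had a correlation of deviations over 0.1 (0.0508 to 0.255). With the replicate number as a block the calls were 4021, 6381, 9059, 6324, 8675 and 3072. As a hint from the data, 29 of 36 comparisons matched a sample best with its own number, where chance would match 1 of 3. In all 4 groups 808 of 10026 genes (8.06%, with 3.70% by chance) were highest in the same number, and Eps8l1 (replicate 3) and Capn11 (replicate 1) were so by at least 1.5-fold. Capn11 was at 17.4, 0.0407 and 2.12 CPM in IL-2 + IL-15 replicates 1 to 3, with the same order of replicates in every group. Same-numbered samples may thus share an origin, which the rule does not exclude and the main fit does not use. In 10 splits of the 6 libraries of each comparison, too few for a share under 0.05, the real split gave 2611, 6275, 8813, 6757 and 7704 genes, 1 split of each set gave as many, and the highest other split gave 0 in each by edgeR (1405, 264, 93, 210 and 184 at an unadjusted p under 0.05). Each of the other splits mixes libraries of both groups, which puts the effect of the treatment into the residual spread. Their 0 calls were thus nearly fixed in advance and do not settle whether chance can be excluded. Depth of 18300206 to 33477037 counts limits genes of few counts, where folds rest on the prior count.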

Other observations

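The comparisons of B cell genes with Ighm, the shift under other scalings and the neighbours with different names were tests chosen only after the results were seen, and the genes in this part were chosen after their values were seen unless the naming rule took them. Igha, an immunoglobulin heavy chain gene, rose from 1.43 ± 0.0415 CPM in IL-2 + IL-15 to 380.1 ± 19.1 in TGFβ and 512 ± 82.7 in TGFβ + RA (ENSMUSG00000095079, chromosome 12, 113254830 to 113260236, GRCm38), and Ighm from 353 ± 50.2 to 1371 ± 16.6 and 2074 ± 249. The gamma delta T cell receptor genes Tcrg-C2 and Tcrg-C4 rose too, Tcrg-C2 from 97.6 ± 21.1 to 314 ± 20.8 and 471 ± 29.0 CPM (1.68 ± 0.17 with TGFβ) and Tcrg-C4 by 1.42 ± 0.18 with TGFβ. Of the same list of gamma delta T cell markers Trdc, the constant region gene of the delta chain, fell, by 0.70 with TGFβ (adjusted p = 0.0269, with 0.000630 to 0.111 over the alternatives but glmTreat, which lost the call) and by 1.27 with both factors (4.2e-04). The mast cell protease Mcpt1 was at 30.4 ± 17.6 CPM in TGFβ and 90.7 ± 47.8 in TGFβ + RA, with 0.134 in IL-2 + IL-15.

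Vipr1, a receptor for vasoactive intestinal peptide, was at 17.7 ± 4.92 CPM in IL-2 + IL-15 and 0.787 in RA (-4.48 ± 0.32), while its paralog Vipr2 went from 0.623 to 12.3 ± 4.13 (4.27 ± 0.32) and reached 74.1 ± 12.1 in TGFβ + RA. The adenylate cyclase Adcy6 fell with RA from 80.4 ± 7.74 to 13.3 ± 8.90 CPM (-2.62 ± 0.29), and Adcy5 rose with TGFβ from 0.143 to 42.0 ± 5.55 CPM. Adjusted p was at most 1.9e-05 for these 4 changes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with n = 3 in each group.

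The rise of Ighm and Igha was weighed against B cells in the cultures, which would bring their other transcripts with these genes. Cd79a, Ms4a1, Pax5 and Igkc, which B cells express, reached at most 0.163% of the Ighm counts in any library with TGFβ, and Igkc had 48, 52 and 55 counts in the TGFβ libraries and 0 in RA and TGFβ + RA. Of the 8 genes of the fixed B cell list besides the heavy chain genes, 1 reached 1% of the Ighm counts, namely Cd79b (0.911% to 2.20%, and a rise of 0.98 ± 0.10 with TGFβ), while Cd22 changed by -2.52 ± 0.40 with TGFβ and -5.53 ± 0.59 with both factors and Blnk and Fcer2a had 0 counts, which argues against B cells as the source. Jchain rose from 0.569 to 6.58 CPM before TMM scaling with TGFβ and was at 0.689 in TGFβ + RA, so a small share of cells of the B lineage may contribute. Transcription of the constant region genes in T cells was not tested and stays open, as do reads of the opposite strand, since the strand setting of the counting is not known.

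Ribosomal protein genes were lower with TGFβ, with a median log2 fold change of -0.68 over 94 genes, 82 of them called lower and 2 higher by edgeR's quasi-likelihood test. For both factors the median was -0.83. Correcting every library for a smooth trend in exon length and GC content left the TGFβ median at -0.60, with quartiles of -0.72 and -0.46 and 81 genes called lower, which argues against such a trend as the whole cause. Other scalings moved the median of all genes by at most 0.0641, and the ribosomal median was -0.61 with library totals alone. The choice among these scalings is thus unlikely to be the source. DESeq2 size factors, like TMM, centre most genes near 0 by construction, and all scalings tried are relative. A change in the total RNA of a cell was therefore not tested. With RA alone the ribosomal median was 0.07. The cause stays open.

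Of the 5 genes with the highest interaction under the naming rule, with a mean of at least 5 CPM, Heatr9 and Ccl5 lie 3.60 kb apart on chromosome 11 and Oas2 and Dtx1 18.4 kb apart on chromosome 5, which prompted the hypothesis that neighbouring genes share the interaction. Over 7771 pairs of neighbouring tested genes within 50 kb, the interaction log2 fold changes had a correlation of 0.171, above all of 1000 shuffles of the genes within chromosomes (-0.0386 to 0.0379). The correlation was 0.145 over the 7202 pairs whose symbols differ in their first 3 letters, so that families recognised by name alone do not carry it. Pairs whose gene bodies overlap were left out, so reads shared by such pairs cannot give this correlation. Shared regulation and read-through may each contribute and were not told apart.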
